A study of Mus musculus with 12 samples.

How the data were processed

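The study dissected hearts of CD1 mouse embryos at embryonic day 16.5, peeled off the outer layers at the base of the great arteries and over the ventricles, and pooled each kind of tissue by litter, per the labels' protocols. RNA was purified with a column kit and made into polyA libraries with the NEBNext Ultra kit, which were sequenced as single reads of 50 bases on an Illumina instrument, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, cutadapt 1.3, RSEM 1.2.3 and the genome build GRCm38. The normalization tool and any filter on genes are not given in the sources used here.

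The deposited table, of 17637 genes in 12 libraries, held a normalized signal that was made by the authors and is not named in the table. Its values were (whole reads + 0.5) as CPM of a scaled library size, which was found from the values: 100% of the 211644 values were whole reads within 0.02 reads, 59971 of them under 50 reads. RSEM estimates need not be whole, so they had been rounded before this step or counted another way. Column sums ran from 982252 to 1067980, so the signal was not plain CPM. Of the genes, 34 had 0 reads in all 12 libraries. Single reads without strand marking do not separate a gene from an antisense partner, and reads of near-identical copies can be divided between them.

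Gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38, matched on the gene identifiers (17468 of 17637 matched, 203 without a symbol, 15 symbols on more than 1 identifier). The design had planned edgeR on counts as the first choice and limma for normalized values. The table held another unit than counts, so the limma plan was used, and edgeR on the recovered reads was added as an alternative. The planned normalization alternatives were run in the limma fit.

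Genes with a mean value of at least 1 were tested (14779, with 2858 below that minimum) by limma 3.58.1 in R 4.3.3, with a trended and robust prior, on log2(value + 1), where 1 is the pseudocount. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05, and tests were two-sided unless named as one-sided. Gene lists, 35 in number and 9 of them primary, were fixed before the data were examined, as were the tests, the rule for named genes and most of the other settings tried. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, on lists with at least 3 tested members. A gene can stand in more than 1 list. The rule named the 10 genes with the largest difference in each direction (mean value of at least 5, past the threshold, same direction in 6 litters, no predicted-gene symbols), up to 3 members per direction of each list with the smallest p (the 2 highest where none passed), 15 focal genes, and the 5 smallest p in each direction. Of these genes, 1 is not reported here. Shares of reads were compared by exact permutation over 924 assignments of the 12 libraries, whose smallest p is 0.002165.

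The litter number pairs the libraries, since the labels say that the pools of a litter were made separately from the same litter. Deviations from the group means correlated by 0.215 on average within litters and -0.043 between litters, and 3 of 6 artery libraries correlated best with their own litter. The test without the block was the planned one, and the litter block was an alternative. Litters are separate pools of animals, so p-values measure the spread between pools. Lane numbers were read from the library descriptions. They may belong to different flow cells.

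The procedure was tested on simulated data with 200 genes changed between artery and ventricle and 14741 genes tested. It recovered 24.5% of genes changed by 1.5-fold, 90% of those changed by 2-fold and 100% of those changed by 4-fold or 8-fold, with 11 false calls among 166 (6.63%). The simulated reads had the same dispersion (spread beyond sampling noise) of 0.05 for all genes. They had no litter effect, no GC trend and no library that stood apart, so these rates may not hold for the real libraries. No pair of libraries of the same group agreed within sampling noise (lowest chi-square per degree of freedom 10.6). Pairs of an artery and a ventricle library were not compared in this way. Depth was 6.77 to 22.1 M reads per library, and depth, GC content (from the annotation's transcripts, for 99.3% of tested genes) and doubted libraries were varied as alternatives. DESeq2 1.42.0, edgeR 4.0.16 and limma-voom were run on the recovered reads. Every column of per-sample values was used.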

Results

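RNA was measured in outer layers peeled from the hearts of wild-type CD1 (an outbred stock) mouse embryos at stage E16.5 (days of gestation). The artery group held the mesothelium, the thin epithelial covering, and the tissue just under it at the base of the great arteries. The ventricle group held the epicardium and subepicardium of the ventricles. Each group had 6 libraries, and each library was a pool of the embryos of 1 litter, so that litters 1 to 6 each gave 1 artery and 1 ventricle library. The deposited table held 17637 genes in normalized values (CPM of a scaled library size), from which whole read numbers were recovered. Read totals were 6.77 M reads in artery 1, 7.97 M in artery 6 and between 16.45 and 22.1 M in the other 10 libraries. The means were 14.2 ± 5.37 M in artery and 18.4 ± 2.12 M in ventricle (SD, n = 6 each, exact permutation p = 0.136). The first principal component held 47.28% of the variance and separated the groups, with artery 4 nearest to the ventricle libraries, and the second (23.79%) set artery 1 apart. Correlations of log values were 0.978 to 0.991 between ventricle libraries and 0.910 to 0.982 between artery libraries.

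**Figure D1:**
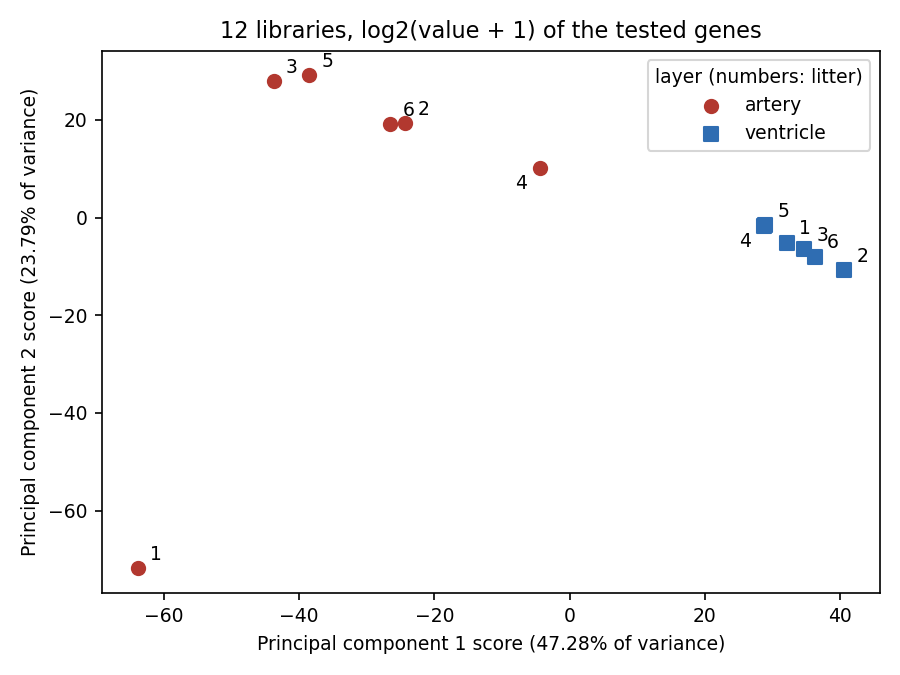
Scores of the 12 libraries on principal components 1 (x axis, 47.28% of the variance) and 2 (y axis, 23.79%), computed on log2(value + 1); circles are artery, squares ventricle, and numbers give the litter. Artery 4 sits at -4.32 on the first component, between the other artery libraries (-24.3 or below) and the ventricle libraries (28.7 or above), and artery 1 sits at -71.8 on the second.

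The series sets the artery layers against the ventricle layers, and its title concerns a vasculogenic niche derived from the second heart field, the progenitor population that builds the outflow tract and the base of the great arteries. The artery layers carried far more RNA of contractile vascular genes and of several secreted factors. The Wnt antagonist Sost (11:101962458-101967015 in GRCm38, minus strand) was at 180 ± 44.2 in artery and 1.48 ± 1.29 in ventricle (SD, n = 6 each), a log2 difference of 6.30 ± 0.28 (SE). Smooth muscle myosin Myh11 followed at 5.78 ± 0.25 and the actin nucleator Lmod1 at 5.08 ± 0.18. The other largest positive differences were those of Acan, the proteoglycan of cartilage (5.01), Smoc1 (4.96), the angiotensin receptor Agtr2 (4.75), the enkephalin precursor Penk (4.596), the neurotrophin receptor Ntrk2 (4.56), Osr2 (4.48) and Pi16 (4.40). Negative differences were smaller. Myoglobin (Mb) was lower in artery by a log2 difference of -2.50 ± 0.51, the neuropeptide receptor Adcyap1r1 by -2.46 ± 0.43 and complement C3 by -2.36 ± 0.50, followed by Kcnd2 (-2.32), Ckmt2 (-2.30), Myo5b (-2.25), Irx4 (-2.24), Chst4 (-2.23), Dpp4 (-2.20) and Aqp4 (-2.16). Lgr6 (3.82 ± 0.14) and the angiotensin converting enzyme Ace (4.02 ± 0.17) joined Lmod1, Smoc1 and Myh11 as the genes higher in artery with the smallest p. Sox3 (-1.55 ± 0.15), Rhox5 (-1.86 ± 0.21), the epicardial factor Tcf21 (-0.90 ± 0.10), Ckmt2 and Lrrc1 (-1.22 ± 0.14) were those lower in artery with the smallest p. All of these genes had adjusted p under the threshold (limma) and the same direction in 6 of 6 litters. For the genes with the largest differences both were conditions of the naming rule. Differences are on the log2(value + 1) scale, which understates the change of genes with low values.

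Across 14779 tested genes, 3556 (24.06%) passed adjusted p 0.05 with limma, 1810 higher and 1746 lower in artery. With at least a 2-fold difference on that scale, 962 genes passed, 563 higher and 399 lower. Of the 3556 genes, 2982 had the same direction in all 6 litters, and the 2 groups did not overlap for 1752 genes (11.9% of those tested, where chance gives 0.216%). Within lane 1, 320 genes passed, 219 of them higher, and within lane 2, 1362 passed, 1019 of them higher, on fewer libraries. The count was 2069 without litter 3 and 5118 without artery 1 and artery 4, the libraries that stood apart.

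Among 35 gene lists fixed in advance, 21 passed adjusted p 0.05 by camera with a preset correlation of 0.01, 13 higher and 8 lower in artery. With a correlation estimated per list, 0 lists passed by camera (7 at an unadjusted p under 0.05), while 27 passed by fry. The counts of members past the test were also recomputed in 18 omissions of 1 litter or 1 library.

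**Figure D2:**
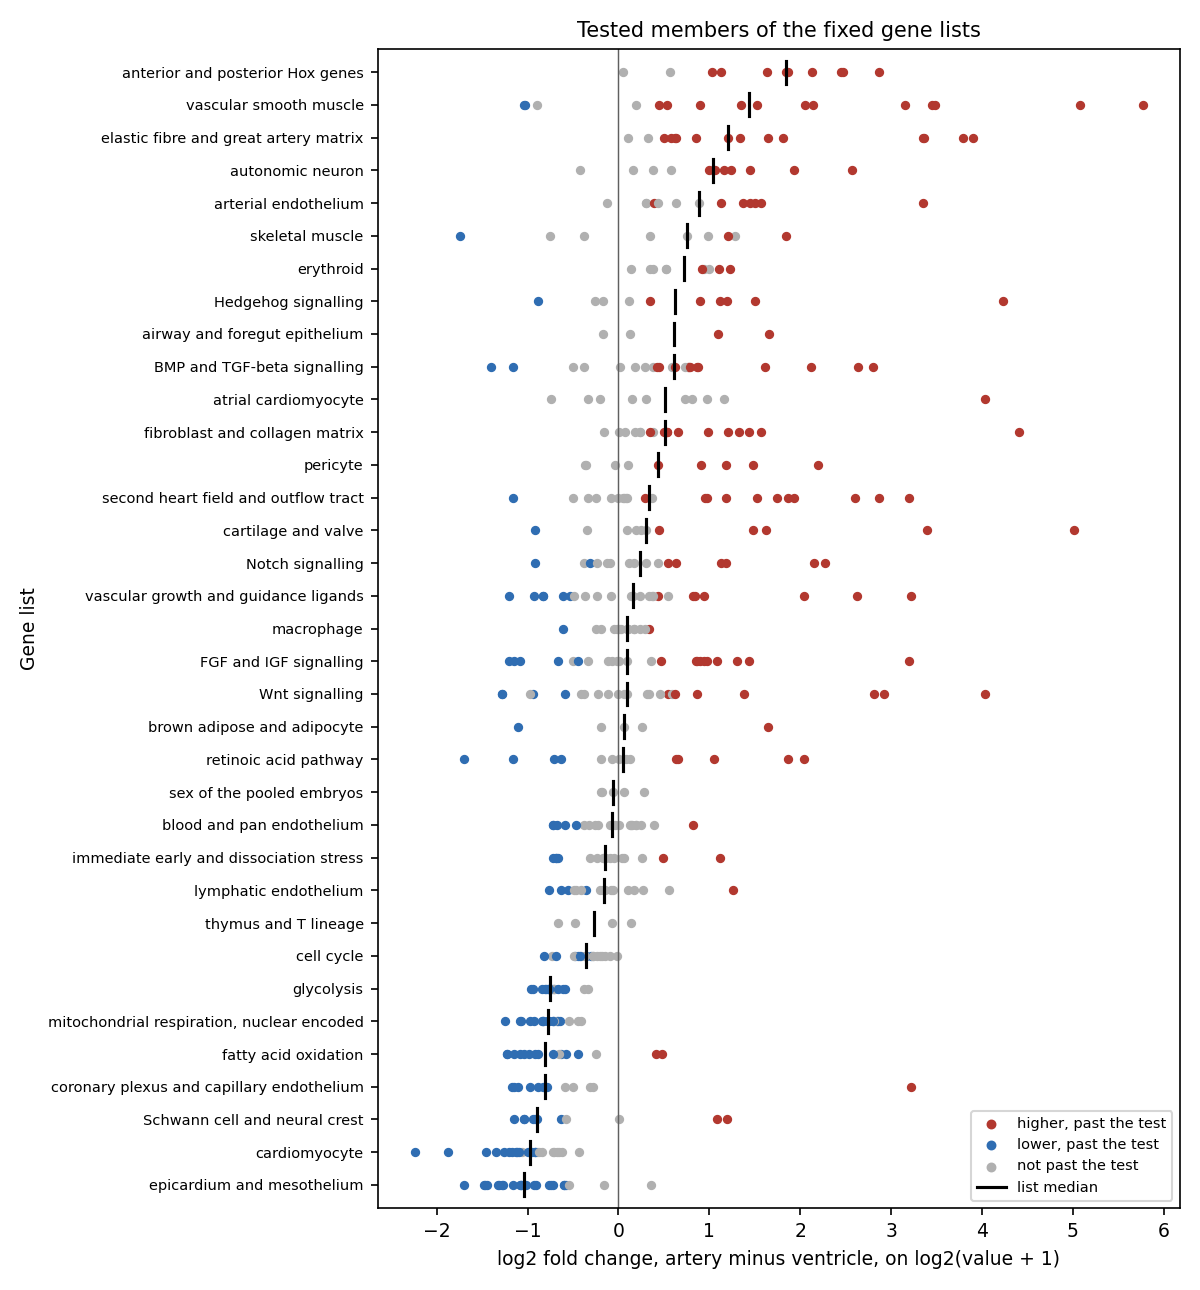
Log2 fold change, artery minus ventricle on log2(value + 1) (x axis), of the tested members of the 35 fixed gene lists (y axis, ordered by median); 1 point per gene, red where higher and blue where lower past adjusted p 0.05, grey where not past it, with a black bar at the list median. Medians run from -1.04 for epicardium and mesothelium to 1.85 for the Hox genes.

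Genes of the second heart field and outflow tract were mostly higher in the artery layers or not past the test. Isl1 (13:116298281-116309689, minus strand), the LIM-homeodomain factor that marks second heart field progenitors, was at 11.7 ± 3.76 in artery and 1.14 ± 0.948 in ventricle, a log2 difference of 2.61 ± 0.27 (SE, adjusted p = 1.02e-05, limma). Isl1 is also expressed in autonomic neurons, and 7 of 12 autonomic neuron genes were higher in artery and 0 lower. Fgf10, a growth factor made by second heart field progenitors, was higher by 3.19 ± 0.33, Hoxa3 by 2.87 ± 0.23, Foxc2 by 1.74 ± 0.14 and Foxc1 by 1.53 ± 0.12. Tbx1 was at 10.1 ± 1.85 and 9.79 ± 2.27, with adjusted p = 0.86, and the cardiac factor Nkx2-5 was lower in artery by -1.16 ± 0.32 (call lost in 1 of 18 omissions). Of 22 tested members 11 were higher, 1 lower and 10 not past the test (11 higher and 2 lower adjusted over the list alone). The list passed camera at adjusted p = 2.94e-05, with adjusted p = 0.145 with an estimated correlation.

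Homeobox genes of the Hox clusters, which set position along the body axis, were higher in artery for 9 of 11 tested members (10 adjusted over the list alone) and lower for 0. Hoxa2 (2.47 ± 0.22) and Hoxb4 (2.13 ± 0.21) stood beside Hoxa3. The list had adjusted p = 9.73e-09 by camera and adjusted p = 0.145 with an estimated correlation. In the Hedgehog list, 6 of 10 members were higher and 1 lower in artery (6 and 1 adjusted over the list alone). The transcriptional target and effector Gli1 was higher by 4.23 ± 0.22 and the co-receptor Boc by 1.11 ± 0.11, while the co-receptor Gas1 was lower by -0.89 ± 0.20 (adjusted p = 0.00186 for the list by camera, adjusted p = 0.256 with an estimated correlation).

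Epicardial and mesothelial genes were lower in artery. The retinoic acid synthesis enzyme Aldh1a2 (9:71215789-71296243, plus strand) was at 109 ± 58.7 in artery and 332 ± 57.4 in ventricle, a log2 difference of -1.70 ± 0.23 (SE, adjusted p = 0.000138, limma). The epicardial factor Wt1 (2:105126529-105173616, plus strand) was lower by -1.45 ± 0.25, the tight junction gene Cldn15 by -1.47 ± 0.24, Tcf21 by -0.90 ± 0.10, Tbx18 by -0.60 ± 0.17 and the uroplakin Upk3b by -0.60 ± 0.19. Both groups still held these RNAs, with Upk3b at 845 ± 232 in artery, and the call of Upk3b was lost in 12 of 18 omissions of 1 litter or 1 library and that of Tbx18 in 3. Of 24 members, 21 were lower, 0 higher and 3 not past the test (22 lower adjusted over the list alone; 13 lower without litter 6). As a set these genes had adjusted p = 1.99e-09 by camera and adjusted p = 0.301 with an estimated correlation. In artery 4, Aldh1a2 reached 7.84 on the log2 scale, against 6.35 to 6.57 in the other 5 artery libraries.

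Retinoic acid genes went both ways. The binding proteins Crabp2 (2.04 ± 0.18) and Crabp1 (1.87 ± 0.23) and the receptor Rarg (1.05 ± 0.14) were higher in artery, while Aldh1a2, Aldh1a1 (-1.16 ± 0.26) and Rbp4 (-0.71 ± 0.13) were lower. Of 14 members 5 were higher, 4 lower and 5 not past the test, the same numbers adjusted over the list alone, and the list had adjusted p = 0.499 by camera.

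Contractile and elastic genes of the vessel wall were higher in artery. Beside Myh11 and Lmod1, the smooth muscle gene Tagln was higher by 3.45 ± 0.23, and 12 of 16 smooth muscle genes were higher, 2 lower and 2 not past the test (12 and 3 adjusted over the list alone). The lower members, Pcp4l1 (-1.03 ± 0.24) and Casq2 (-1.04 ± 0.34), the latter a calcium-binding protein of the cardiac sarcoplasmic reticulum, are also expressed in heart muscle. The call of Casq2 was lost in 11 of 18 omissions, and 1 member was lower without litter 2. Elastin (Eln, 5:134702593-134747323, minus strand) was higher by 3.79 ± 0.21, the microfibril-associated Ltbp2 by 3.90 ± 0.25 and Fbln5, which assembles elastic fibres, by 3.35 ± 0.18. Of 15 elastic fibre and matrix genes 13 were higher, 0 lower and 2 not past the test (14 higher adjusted over the list alone). The smooth muscle list had adjusted p = 2.85e-09 by camera and adjusted p = 0.0703 with an estimated correlation. The elastic list had adjusted p = 7.1e-13 by camera and adjusted p = 0.118 with an estimated correlation.

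Other mesenchymal lists were higher in artery as well. Among 18 fibroblast and collagen genes 11 were higher and 0 lower, over all genes and adjusted over the list alone, led by Pi16, Bgn (1.44 ± 0.14) and Vcan (1.57 ± 0.16). The list had adjusted p = 1.19e-06 by camera and adjusted p = 0.256 with an estimated correlation. Of 9 pericyte genes 5 were higher and 0 lower by both adjustments, with Cspg4 (1.48 ± 0.16), Notch3 (1.18 ± 0.17) and Pdgfrb (0.90 ± 0.13) past the test. That list had adjusted p = 0.00714 by camera and adjusted p = 0.307 with an estimated correlation, and its call was lost without artery 1 and either artery 4 or artery 6. Among 11 cartilage and valve genes 5 were higher and 1 lower by both adjustments, with Acan, Col9a1 (3.40 ± 0.41) and the tendon gene Tnmd (1.48 ± 0.21) higher and Col11a1 lower (-0.92 ± 0.26, call lost in 3 of 18 omissions). That list had adjusted p = 0.00318 by camera and adjusted p = 0.301 with an estimated correlation.

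**Figure D3:**
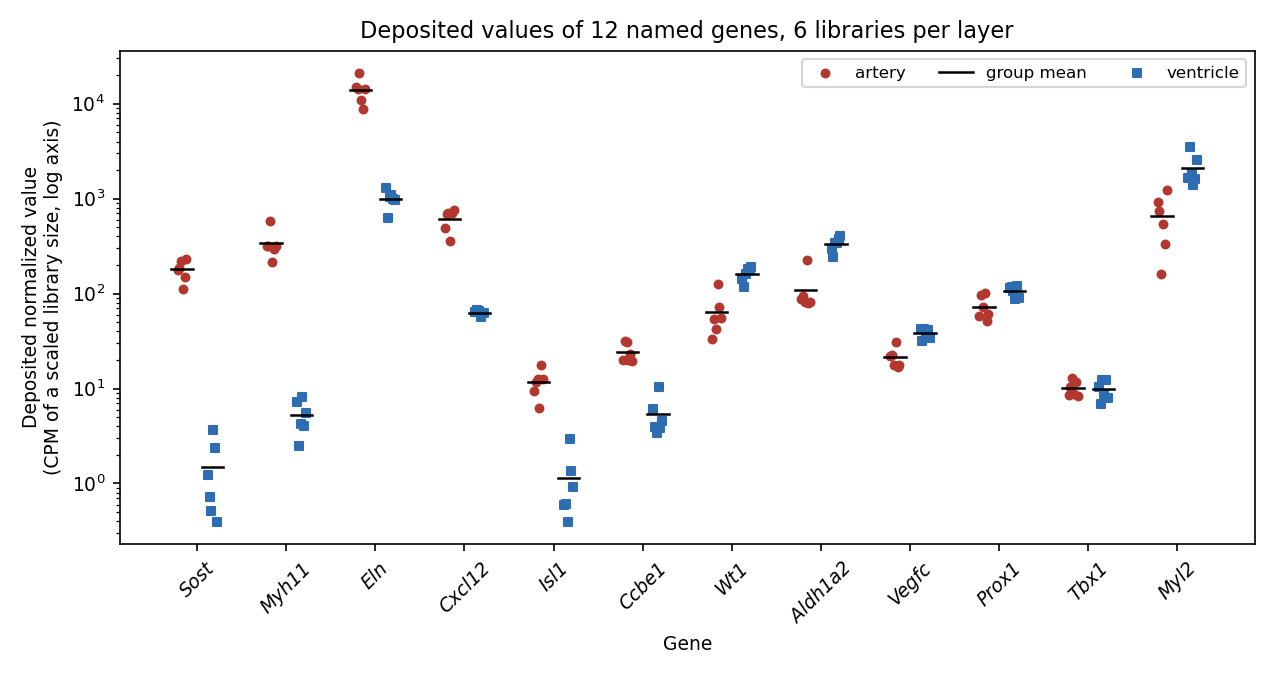
Deposited normalized values (CPM of a scaled library size, log y axis) of 12 genes (x axis) in the 6 artery (circles) and 6 ventricle (squares) libraries, with black bars at the group means. The 6 artery libraries lie above the 6 ventricle libraries for Sost, Myh11, Eln, Cxcl12, Isl1 and Ccbe1, while Tbx1 has means of 10.1 and 9.79.

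Lymphatic endothelial genes, the genes of the vessels named in the study's title, did not move together. Prox1, the master regulator of lymphatic identity, was at 73.1 ± 20.6 in artery and 105 ± 13.6 in ventricle, a log2 difference of -0.56 ± 0.16 (SE, adjusted p = 0.0232, limma) and lower in 5 of 6 litters. Fgl2 (-0.76 ± 0.13), Pdpn (-0.64 ± 0.21) and Sox18 (-0.36 ± 0.10) were also lower, and the integrin subunit Itga9 was higher (1.26 ± 0.15). Which cells of the pooled layers held each RNA was not determined. Most epicardial (21 of 24) and heart muscle genes (14 of 24) were lower in artery too, so these calls cannot be assigned to lymphatic endothelium. The receptor Flt4 (-0.20 ± 0.18, adjusted p = 0.45; -0.32 without artery 4 and -0.071 without litter 5) and Lyve1 (-0.46 ± 0.17, adjusted p = 0.0679) did not pass, though Lyve1 passed without artery 4 (-0.57). The call of Prox1 was lost in 7 of 18 omissions, that of Pdpn in 11 and that of Sox18 in 5. Of 18 members 1 was higher, 4 lower and 13 not past the test by both adjustments (1 lower without litter 3, 6 lower without artery 1 and artery 4), and the list had adjusted p = 0.266 by camera.

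Blood and general endothelial genes were mostly not past the test (14 of 20), with 5 lower, Esam (-0.72 ± 0.13), Robo4 (-0.68 ± 0.15) and Ets1 (-0.73 ± 0.18, call lost in 1 of 18 omissions) among them, and Plvap higher (0.82 ± 0.17), by both adjustments (2 lower without litter 3). That list had adjusted p = 0.449 by camera. Arterial endothelial genes were higher in artery for 7 of 13 members (9 adjusted over the list alone) and lower for 0, among them the ephrin Efnb2 (1.57 ± 0.13) and Bmx (1.502 ± 0.15). The higher members also included Fbln5 and Stmn2, which stand in the elastic fibre and autonomic neuron lists too. The count is thus not of endothelial genes alone. The arterial endothelial list had adjusted p = 3.29e-07 by camera and adjusted p = 0.118 with an estimated correlation. Coronary plexus and capillary genes were lower for 7 of 12 members (9 adjusted over the list alone), such as the lipid-binding proteins Fabp4 (-1.10 ± 0.21) and Fabp5 (-0.97 ± 0.13) and the ligand Apln (-1.17 ± 0.22). The exception was the chemokine Cxcl12 (6:117168535-117181367, plus strand), at 616 ± 158 in artery and 63.1 ± 3.41 in ventricle and higher by 3.22 ± 0.16. The list had adjusted p = 0.00148 by camera and adjusted p = 0.301 with an estimated correlation.

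Secreted factors that guide vessels split between the layers. Vegfc (8:54077606-54187096, plus strand), the growth factor for lymphatic vessels, was lower in artery by -0.83 ± 0.14 (SE, adjusted p = 0.000739, limma), from 38.1 ± 4.54 in ventricle to 21.3 ± 5.34. Its extracellular partner Ccbe1 (18:66045302-66302741, minus strand) was higher by 2.04 ± 0.22 (adjusted p = 1.86e-05), at 24.2 ± 5.62 and 5.36 ± 2.66. Angpt2 was higher by 2.62 ± 0.16, Angpt1 lower by -1.21 ± 0.31 and Sema3d lower by -0.93 ± 0.27, with the call of Angpt1 lost in 1 of 18 omissions and that of Sema3d in 3. Of 25 members 7 were higher, 6 lower and 12 not past the test (10 higher and 7 lower adjusted over the list alone; 2 lower without litter 3). The list did not pass camera (adjusted p = 0.0974, and adjusted p = 0.301 with an estimated correlation), but passed fry (adjusted p = 0.000174), which tests whether the genes move one way on balance. Unlike camera, fry does not set the members against the other genes, and it passed 27 of the 35 lists.

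Heart muscle genes were lower in artery. Ventricular myosin light chain Myl2 was at 655 ± 391 in artery and 2084 ± 800 in ventricle (log2 difference -1.87 ± 0.42, SE, adjusted p = 0.00535, limma), the ventricular factor Irx4 was lower by -2.24 ± 0.35 and Hey2 by -0.92 ± 0.21. Of 24 members 14 were lower, 0 higher and 10 not past the test (17 lower adjusted over the list alone; 18 lower with the litter as a block; 4 lower without litter 3). As a set these genes had adjusted p = 1.15e-06 by camera and adjusted p = 0.326 with an estimated correlation. These genes took 1.34 ± 0.622% of the reads in artery and 2.65 ± 0.916% in ventricle (SD, n = 6, exact permutation p = 0.0108, adjusted 0.0292 over 3 shares), lower in artery in 6 of 6 litters. Among 10 atrial genes Dkk3 was higher (4.03 ± 0.25), 0 were lower and 9 did not pass by both adjustments (3 higher with the litter as a block), and the list had adjusted p = 0.0979 by camera. It passed by fry (0.0282) and without litter 5 (adjusted p = 0.0186 by camera), and stood at 0.427 without artery 1. With an estimated correlation the atrial list had adjusted p = 0.502 by camera.

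Energy metabolism genes were lower in artery, where the heart muscle share of reads was also lower. Of 20 nuclear genes of mitochondrial respiration 16 were lower and 0 higher (17 lower adjusted over the list alone), such as Sdha (-0.97 ± 0.19), Cox5a (-1.09 ± 0.21) and Idh3a (-1.07 ± 0.23). Of 16 glycolysis genes 13 were lower and 0 higher (14 lower adjusted over the list alone; 8 without litter 3), including the glucose transporter Slc2a1 (-0.96 ± 0.17), Pfkl (-0.80 ± 0.15) and Pgam1 (-0.66 ± 0.11). Of 16 genes of fatty acid oxidation 12 were lower and 2 higher (13 and 2 adjusted over the list alone; 4 and 0 without litter 3), with Acaa2 (-1.22 ± 0.15), Hadhb (-0.89 ± 0.19) and the coactivator Ppargc1a (-0.98 ± 0.24) lower and Cpt1a (0.48 ± 0.14) and Slc27a1 (0.41 ± 0.12) higher, calls lost in 4 and 7 of 18 omissions. By camera the adjusted p was 4.15e-08 for respiration, 2.61e-07 for glycolysis and 0.00025 for fatty acid oxidation. The first 2 had adjusted p = 0.301 with an estimated correlation and the last adjusted p = 0.326 with an estimated correlation. Of 20 cell cycle genes 7 were lower and 0 higher (15 lower adjusted over the list alone; 3 without litter 3 and 12 without artery 4), among them Rrm2 (-0.82 ± 0.16), Ccnb1 (-0.48 ± 0.10) and Ccnb2 (-0.44 ± 0.11). That list had adjusted p = 5.76e-05 by camera and adjusted p = 0.307 with an estimated correlation.

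Genes of nerve cells were higher in artery, while those of glia went both ways. Of 12 autonomic neuron genes 7 were higher in artery and 0 lower by both adjustments, with the synaptic gene Syt1 higher by 2.57 ± 0.25 and the stathmins Stmn4 by 1.93 ± 0.20 and Stmn2 by 1.45 ± 0.22. The list had adjusted p = 1.78e-05 by camera and adjusted p = 0.127 with an estimated correlation. Of 11 Schwann cell and neural crest genes 7 were lower and 2 higher by both adjustments, with Erbb3 (-1.03 ± 0.19), Sox10 (-1.04 ± 0.21) and Cdh19 (-0.94 ± 0.20) lower and Dhh (1.196 ± 0.20) and S100b (1.09 ± 0.20) higher. That list had adjusted p = 0.0407 by camera, adjusted p = 0.326 with an estimated correlation, and adjusted p = 0.0552 with the litter as a block, which ends its call. The call was also lost in 7 of 18 omissions (highest 0.0731, without litter 3).

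Markers of other tissues that a dissection could hold were mostly not past the test, as were most of all tested genes, of which 24.06% passed. These counts thus cannot show that the layers were free of such tissues. Haemoglobin and other erythroid genes were higher for 3 of 10 members and lower for 0 by both adjustments (5 higher with the litter as a block, 0 without litter 2), with Hba-a1 (1.10 ± 0.35), Hbb-y (1.22 ± 0.34) and Alas2 (0.92 ± 0.31) past the test. The call of Alas2 was lost in 13 of 18 omissions, that of Hba-a1 in 10 and that of Hbb-y in 2. Reads of Hba-a1 and of its near-identical copy Hba-a2 cannot be told apart with certainty. As a set these genes had adjusted p = 0.00714 by camera and adjusted p = 0.326 with an estimated correlation, and their call was lost without artery 1 and artery 6. Haemoglobin took 0.65 ± 0.578% of reads in artery and 0.27 ± 0.0646% in ventricle (exact permutation p = 0.0195, adjusted 0.0292), higher in artery in 6 of 6 litters. The difference of 0.38 percentage points was 0.152 without artery 6, and its exact p missed the threshold in 8 of 18 omissions (0.126 without ventricle 2) and without artery 1 and artery 6 (0.081). Mitochondrially encoded genes took 2.54 ± 0.949% and 2.98 ± 0.407% (exact permutation p = 0.377), and the difference of -0.446 percentage points was -0.0684 without artery 1, where the share was 0.653%. Of 15 macrophage genes C1qb was higher (0.34 ± 0.11) and Csf1r lower (-0.61 ± 0.17; 0 higher and 1 lower adjusted over the list alone), with adjusted p = 0.548 by camera, and the call of C1qb was lost in 10 of 18 omissions and that of Csf1r in 3. Of 4 thymus and T lineage genes 0 passed by either adjustment (Lck -0.48 ± 0.29, Ccl25 0.14 ± 0.17), with adjusted p = 0.621 by camera. In omissions Lck ranged from -0.626 (without litter 6) to -0.255 (without ventricle 4). Ccl25 ranged from 0.019 (without litter 1) to 0.280 (without litter 4). Of 4 airway genes Sftpc (1.66 ± 0.43, call lost in 1 of 18 omissions) and Foxj1 (1.10 ± 0.28) were higher and 0 lower by both adjustments, with adjusted p = 0.179 by camera. Of 5 adipocyte genes Plin4 was higher (1.64 ± 0.22) and Fabp4 lower by both adjustments, with adjusted p = 0.669 by camera. Of 9 skeletal muscle genes Myh3 (1.85 ± 0.55) and Tnnt3 (1.205 ± 0.37) were higher and Tnnt1 lower (-1.74 ± 0.24; 3 higher and 1 lower adjusted over the list alone; 0 higher without litter 5), with adjusted p = 0.499 by camera, and the calls of Myh3 and Tnnt3 were lost in 5 and 8 of 18 omissions.

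Signalling lists held strong single genes. In the BMP and TGF-beta list 12 of 22 members were higher and 2 lower in artery (13 and 2 adjusted over the list alone), with Bmp3 (2.80 ± 0.20), Gdf10 (2.63 ± 0.23) and Ltbp1 (2.12 ± 0.13) higher and Bmp6 (-1.41 ± 0.25) and Bmp5 (-1.16 ± 0.21) lower. The list had adjusted p = 1.87e-05 by camera and adjusted p = 0.118 with an estimated correlation. In the Notch list 6 of 16 members were higher and 2 lower by both adjustments, with the ligand Jag1 (2.27 ± 0.14), Heyl (2.15 ± 0.12) and Hey1 (1.13 ± 0.15) higher and Hey2 and Lfng (-0.32 ± 0.10) lower. The call of Lfng was lost in 12 of 18 omissions, and 1 member was lower without litter 3. That list had adjusted p = 0.00732 by camera and adjusted p = 0.301 with an estimated correlation, and its call was lost without artery 1 and either artery 4 or artery 6. In the Wnt list 7 of 23 members were higher and 4 lower (8 and 4 adjusted over the list alone). The secreted antagonists Sfrp2 (2.81 ± 0.19) and Dkk2 (2.92 ± 0.28) were higher and Rspo1 (-1.28 ± 0.23), Wnt4 (-1.29 ± 0.23) and Wnt2b (-0.94 ± 0.20) lower, with adjusted p = 0.0845 by camera. That list passed by fry (adjusted p = 0.00526) and, by camera, without ventricle 5 (adjusted p = 0.0361, with 0.203 the highest over the omissions). With an estimated correlation the Wnt list had adjusted p = 0.436 by camera. In the FGF and IGF list 10 of 23 members were higher and 5 lower (10 and 6 adjusted over the list alone), with Fgf10, Fgfr1 (1.09 ± 0.12) and Igfbp4 (0.86 ± 0.12) higher and Fgf9 (-1.14 ± 0.14), Spry2 (-1.08 ± 0.15) and Dusp6 (-0.66 ± 0.11) lower, with adjusted p = 0.129 by camera.

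Among 18 immediate early and stress genes 2 were higher and 4 lower by both adjustments, Egr1 (1.11 ± 0.17) and Jun (0.50 ± 0.08) against Atf3 (-0.72 ± 0.11), Ier3 (-0.67 ± 0.10) and Hspa1b (-0.68 ± 0.19, call lost in 3 of 18 omissions) among the lower (2 lower without litter 3), and the list had adjusted p = 0.22 by camera. Of 5 genes that mark the sex of the pooled embryos 0 passed by either adjustment, with Xist at 0.28 ± 0.34 and the Y-linked Ddx3y at -0.06 ± 0.27, and the list had adjusted p = 0.993 by camera. Xist ranged from 0.096 (without artery 5) to 0.551 (without artery 6) in omissions.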

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

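The tests of GC content, of depth and of atrial genes in artery 1 and the test of an exchange in litter 4 were chosen only after those results were seen. For the GC test, the reference of the other libraries was also redefined, to leave artery 1 out, after a first version had been run; in both versions artery 1 had the highest value.

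A library lay far from the other 5 of its group in 30 of 308 groups of values tested (9.74%, where chance gives about 1 in 20). Of these, 11 lay in artery 4 and 2 in artery 1. The groups covered each gene the naming rule gives and the library measures, so they include genes the naming rule chose for their difference.

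Artery 4 lay between the other artery libraries and the ventricle libraries on the first principal component, and its mean correlation was 0.955 with the artery and 0.967 with the ventricle libraries. On the log2 scale it was the highest of the 6 artery libraries for Adcyap1r1 (6.54), Kcnd2 (3.43), Myo5b (7.10), Chst4 (4.59), Dpp4 (7.84), Sox3 (0.70), Lrrc1 (5.78), Aldh1a2 (7.84), Cldn15 (6.31) and Bmp5 (3.21), all lower in artery than in ventricle, and the lowest for Hoxa2 (2.55), which is higher in artery. A full exchange of the 2 libraries of litter 4 is argued against by ventricle 4. Its mean correlation with the other ventricle libraries exceeded that with artery libraries by 0.0444. Of the genes higher in artery, ventricle 4 was the highest ventricle library for some (Agtr2, Ntrk2 and Pi16) and the lowest for Cxcl12. Artery layer tissue in the ventricle pool was not tested. Ventricle layer tissue in the artery pool stays open as a candidate explanation: genes chosen without litter 4 put its share at 46.3% (427 genes higher in artery, interval 44.3 to 49.1) and at 55.0% (427 genes higher in ventricle, interval 48.4 to 59.2), a difference of 0.0867 as a fraction. The intervals come from resampling genes within this 1 library. Genes are not independent replicates, so the intervals do not measure how well the share of the pool is known. A true difference of that litter's tissue was not tested.

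Artery 1 had 2057 genes at 0 reads (495 to 795 in the other artery libraries) and 0.653% mitochondrial reads (2.62 to 3.26% in the others). Lower depth is argued against as the whole cause, since after thinning to equal totals it still had 1.94 times as many genes at 0 reads as the next library. Few molecules behind the reads may be part of the cause, since the spread after GC correction was 1.799 times that of the next library for means under 20. The ratio was 1.25 for means of 20 to 200 and 1.48 for means of at least 200. The latter genes include mt-Co2 and mt-Co3, which had 0 reads in artery 1, and the ratio was not computed without them. It thus cannot decide whether few molecules were the whole cause. The rank correlation of a library's deviation with transcript length was -0.109 in artery 1, but -0.501 in artery 6 and 0.434 in artery 4. Technical trends were thus not particular to artery 1, and that of length was not tested further. GC content may be part of the cause, with a rank correlation across genes of 0.511 (0.19 or less in size in the other libraries). Genes are not independent replicates. GC content was not the whole cause, since after GC correction the spread was still 1.57 times that of the next library. Atrial tissue in the pool may be another part: the 10 atrial genes lay at a median of 1.302 above the other artery libraries after GC correction (quartiles 0.31 and 1.76), 6 of them highest in artery 1 of all 12 libraries, and no biological difference of that litter was tested.

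Other values far from their group were these, on the log2 scale for genes. In artery 5, Sox18 (4.77) and Rbp4 (3.44) were the lowest. In artery 6, Alas2 (6.88) and the haemoglobin share (1.79% of reads) were the highest. In ventricle 2, Fbln5 (6.74), Csf1r (6.63), Sema3d (7.94), Wnt2b (5.77) and Boc (5.62) were the lowest and Ccnb1 (6.30), Ccnb2 (6.04) and Tnmd (0.31) the highest. In ventricle 4, Pi16 (3.86) and Stmn4 (1.71) were the highest, in ventricle 5 Col9a1 (2.96) and Foxj1 (1.02), and in ventricle 1 Bmx (2.00).

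The 52 genes of glycolysis, respiration and fatty acid oxidation had a median log2 difference of -0.77 (quartiles -0.92 and -0.65), with 41 lower past the test. GC content is argued against, since after GC correction the median was -0.75. Fewer cardiomyocytes in the artery layers may account for the pattern: with the mean of the cardiomyocyte genes as a covariate the median was -0.17 (quartiles -0.32 and -0.09) and 2 genes stayed lower past the test. That covariate correlated by -0.69 with the group, so calls of all genes also dropped, to 1222, while the epicardium and mesothelium list kept a median of -1.10. A lower metabolic rate of the artery layers themselves was not tested.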

How the results depend on the processing

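Alternatives chosen after the data were seen were edgeR on the recovered reads with and without the block, recomputed TMM factors, leaving out artery 1 with 6 or with 4, array weights, thinning and GC correction; the others were planned. Of 100 splits of the 12 libraries, 1 (the real one) gave as many genes (3556, highest other 947). The same split alone gave as many 2-fold genes (962, highest other 465). Among the 32 splits that part all litters, the highest other gave 1179 genes. Chance is thus unlikely for these counts but not excluded, since the smallest share possible is 1 in 100, or 1 in 32. The other splits also mix artery with ventricle libraries, which widens the spread within their groups. For the count of lists the splits cannot decide about chance. Of 100 splits 10 gave 21 or more (highest other 25), the real one included. So did 4 of the 32 splits that part all litters, the real one included (highest other 23). The other drawn splits with 21 or more kept 4 or 5 of the 6 artery libraries on 1 side, so they held part of the real contrast. Drawn splits with 3 artery libraries on each side gave 1 to 15 lists. With the replicate block 3619 genes passed, 3309 of them shared, and the block changed no call of a primary list or named gene. Leaving out 1 litter or 1 library gave 2069 (without litter 3) to 4291 genes, and 806 to 1161 2-fold genes; without artery 1 and 6 there were 4769 genes, and without artery 1 and 4 there were 5118 (1170 2-fold). The gene count was 320 within lane 1 and 1362 within lane 2 (2-fold 319 and 594), on fewer libraries. DESeq2 gave 1568 2-fold genes, with another model and filter (17511 genes tested), and a pseudocount of 0.1 alone gave 1181; the cause was not tested further. edgeR gave 3486 genes, and the 2-fold count 1226.

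With an estimated correlation 0 lists passed, with adjusted p = 0.301 for epicardium, 0.145 for second heart field, 0.326 for cardiomyocyte, 0.0703 for smooth muscle and 0.118 for elastic fibre. Lyve1 passed in 7 settings, among them without artery 4 (-0.57), with array weights and with DESeq2, and Xist passed with the same-lane block. Fry also passed the airway (0.0282), FGF and IGF (0.0192) and immediate early lists (0.0232), and the airway list passed with no filter. Besides those named in the results, list calls were lost for Notch with the same-lane block and with GC correction plus the block, for pericyte in lane 2, for erythroid with edgeR and without the cardiomyocyte, haemoglobin and mitochondrial genes, and for Schwann cell with the stricter filter, in lane 1, with a pseudocount of 0.1, with edgeR plus the block and with thinning. Vascular ligands passed with fry (0.000174), edgeR (0.0168), edgeR with the block (0.0183) and without artery 5 (lowest 0.0491, highest 0.161). The haemoglobin difference kept its direction (0.152, without artery 6, to 0.453 percentage points), but its exact p missed the threshold in 8 of 18 omissions. Without artery 1 and 6 the difference was 0.0821 percentage points (exact permutation p = 0.081). The mitochondrial difference (-0.667 to -0.0684 in omissions) was 0.00518 without artery 1 and 4.

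Directions turned only for values not past the test, and the cause was not tested. The retinoic acid list turned lower with the stricter filter (adjusted p = 0.715; 0.377 to 0.685 in omissions). The sex list turned higher with the block (0.939), the same-lane block (0.500004), library size (0.983), the stricter filter (0.924), voom (0.985), lane 2 (0.839), TMM (0.981), without artery 1 and 6 (0.649), without 1 and 4 (0.737), array weights (0.84), thinning (0.98), GC correction (0.684), and GC with the block (0.442); 0.551 to 0.975 in omissions. Adipocyte turned with the same-lane block (0.977), lane 2 (0.755) and without artery 1 and 6 (0.892), skeletal muscle with the stricter filter (0.296) and lane 1 (0.809), and atrial in lane 2 (0.89). The thymus list ranged from 0.401 to 0.856. Tbx1 ranged from -0.048 to 0.12 in omissions, and was -0.047 with thinning and -0.037 with GC correction, alone or with the block. Flt4 was 0.0092 in lane 1. Ccl25 was -0.038 with the same-lane block and -0.15 in lane 2. Ddx3y was 0.13 with the same-lane block and with GC correction, 0.047 with DESeq2, 0.036 in lane 2, 0.058 with edgeR, 0.098 without artery 1 and 6, and -0.22 to 0.15 in omissions.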

Other observations

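The families below and the comparison of mitochondrial genes were chosen only after results were seen; the test of the sex mix was written before its result was seen.

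Among 224 gene families defined by symbol, those with more genes higher in artery than the 12.2% of all tested genes were led by the Adamts family of extracellular proteases and related proteins, where 12 of 18 tested members were higher and 1 lower (median log2 difference 0.96, adjusted p = 4.49e-05, one-sided Fisher's exact test). The Hox family followed with 10 of 14 higher and 0 lower (median 1.38, adjusted p = 0.000104), then the collagens with 14 of 42 higher and 5 lower (median 0.28, adjusted p = 0.0454). The test treats genes as independent, which members of a family are not.

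The mitochondrial genes mt-Co2 and mt-Co3 had 0 reads in artery 1. In the other 11 libraries mt-Co2 had 7973 reads or more and mt-Co3 8223 or more. In artery 1 mt-Co1 had 17881 reads, mt-Nd1 5818 and mt-Atp6 1138.

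The mix of male and female RNA may be related between the pools of a litter, but a correlation cannot show that it was the same. The log2 ratios below were -3.50 in artery and -1.89 in ventricle for litter 5, and -1.42 and -1.57 for litter 4. The log2 ratio of Y-linked genes to Xist correlated between the artery and ventricle pools across 6 litters with Pearson's r = 0.849 (exact permutation p = 0.0361, adjusted 0.0722 over the 2 coefficients) and Spearman's rho = 0.771 (exact permutation p = 0.103, adjusted 0.103). Without the 2 litters whose artery ratio lay farthest from the median r was 0.307. Leaving out such litters narrows the range and by itself lowers r. A relation beyond those litters was thus neither shown nor excluded.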
